A study of Solanum lycopersicum with 18 samples.

How the data were processed

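The series measured transcript levels in tomato fruit pericarp, the fleshy wall of the fruit, on the Affymetrix tomato array, in the variety Pusa Ruby. Wild-type fruit was set against fruit of the ripening-inhibitor mutant rin, which carries a lesion at the MADS-box gene RIN and does not ripen normally. The labels give 3 ages, 35, 40 and 45 days (DAP, spelled out in the labels as days after planting), and 3 biological replicates for each genotype and age, so 18 arrays in 6 groups. For wild type the ages correspond by label to immature green, breaker and red-ripe fruit. The labels number the plants but do not say that every array came from a separate plant, and codes in the titles recur across ages. P-values therefore measure the spread between these samples, which may be partly technical. The general growth and treatment notes in the labels speak of seedlings and shoots, which does not match fruit pericarp. The groups were therefore taken from the sample titles and characteristics alone.

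The deposited table holds 1 intensity per probe set and array on a linear scale, computed with GCOS per the submitters' processing notes, which give no version. The 2% trimmed means of the arrays lay between 327.6 and 348.2, a ratio of 1.063 between the highest and the lowest, so the deposited intensity values had already been brought to a common level. The target of that scaling is not given in the sources used here. Signals ran from 2.04 to 25059, and array medians from 76.62 to 87.23. The highest signal of the 23 negative control probe sets was 6.854, and the 30th percentile of an array lay between 11.3 and 15.34. The number of arrays, 3 in each group, limits the precision of every value.

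All values were taken to log2 without further normalization. Of 10209 probe sets, 108 controls were left out. A further 2384 were left out as dim because they did not exceed their own array's 30th percentile on at least 3 of the 18 arrays, which left 7717. One model with a mean for each of the 6 groups was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend with signal (eBayes), and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A probe set was called at an adjusted p under 0.05, and the tests were two-sided. The comparisons were rin against wild type at each age and averaged over the 3 ages, each pair of ages within each genotype, and the genotype by age interaction, which tests whether a change with age differed between genotypes. Folds are ratios of geometric means. Where an array of the dimmer group lay at or below its own 30th percentile, called dim here, the fold or log2 change is given as "at least" a value. This is the brighter group's geometric mean over that of the dimmer group, with each dim signal raised to that percentile. Its use where only 1 or 2 of the 3 arrays were dim was chosen after seeing the data. Means and standard deviations are of linear signals over 3 arrays.

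Gene names came from the platform's annotation, dated 2007, in which 909 probe sets carry 1 symbol and none carries several, while 9192 are unnamed here. Entrez identifiers matched the RefSeq gene table of assembly SLM_r2.1 for 885 of them, which updated the symbols to 803 genes. After the filter, 687 named probe sets for 635 genes were tested, and for the 41 genes with several probe sets the brightest one represented the gene. None of those 41 genes had probe sets called in opposite directions between rin and wild type at 45 DAP. The gene listed as gad2 also carries the synonym GAME11, a glycoalkaloid gene, so its name is doubtful.

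The test, the filter, the lists and the rule for named genes were fixed before the data were examined. For the main comparisons the rule took the 7 called genes with the largest increase and the 7 with the largest decrease whose arrays did not overlap between the groups. It also took the 3 called members with the smallest adjusted p from each of the 6 lists with the largest share of calls, and RIN. For other comparisons it took the 3 largest in each direction. Genes named outside that rule are said to be so or are given as examples of a list. Of 20 gene lists, 16 had measured members and 8 had at least 5, which were tested with camera at a preset correlation of 0.01. These 8 were ripening regulators, ethylene synthesis, ethylene perception and response, carotenoid and isoprenoid synthesis, cell wall modification, aroma volatile synthesis, sugar and starch metabolism, and defence. Photosynthesis, flavonoid synthesis, heat shock, auxin response, cell cycle, glutamate metabolism, polyamine synthesis and cuticle markers had 2 to 4 measured members and are given as counts. The lists were matched by gene symbols and synonyms only, and the search terms for gene titles planned with them were not applied. The lists of ribosomal proteins, the proteasome and xylem markers held no symbols, and the symbols of the seed markers matched none in the annotation. Ribosomal protein genes such as RPS25 are on the array all the same, and 6 of them are in a translation list added later. A further 11 lists were drawn up from the annotation's symbols after the main results had been seen.

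The alternatives were quantile normalization, median centring, no filter on dim probe sets, a filter at the 50th percentile, log2 of the signal plus 32, eBayes without the trend, only the arrays of the groups compared, the replicate number as a block, the code in the titles as a random block, a 2-fold threshold, each array left out in turn, and, for lists, the mean of all probe sets per gene, an estimated correlation and fry. Others were added after seeing the data. These averaged replicates 2 and 3 of rin at 45 DAP as 1 array, left out the first arrays of rin at 40 and 45 DAP together, raised signals below an array's 30th percentile to it, or took RIN, the mutated gene, out of the list of ripening regulators, which left 4 genes. Where leaving out 1 array moved a fold by over 1.5 times, the fold without it is given, with dim signals raised in the same way. The model was tested on simulated data for rin against wild type at 45 DAP, with 100 of 7717 probe sets changed at each size. It recovered 32% of those changed by 1 on the log2 scale and 78% of those changed by 2, with 2 false calls. The simulation was drawn once, with independent normal noise and few changed probe sets, so these values need not hold for the real comparisons. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.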

Results

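Transcript levels were measured in fruit pericarp of wild-type tomato and of the rin mutant at 35, 40 and 45 DAP, with 3 arrays in each of the 6 groups. The design asked how the transcriptome of ripening fruit differs between the genotypes at matched ages. Between 4667 and 4829 probe sets per array had a signal above 100. On the first principal component, which held 52.3% of the variance, the wild-type arrays at 40 and 45 DAP lay between 49.9 and 101. All arrays at 35 DAP lay between -65.3 and -46.4. The rin arrays at 45 DAP lay in between, from -9.47 to 16.0. Replicate 1 of rin at 40 DAP, at -7.36, lay apart from replicates 2 and 3, at -55.0 and -54.0. Replicates 2 and 3 of rin at 45 DAP had the highest correlation of any replicate pair (r = 0.991, across probe sets).

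**Figure D1:**
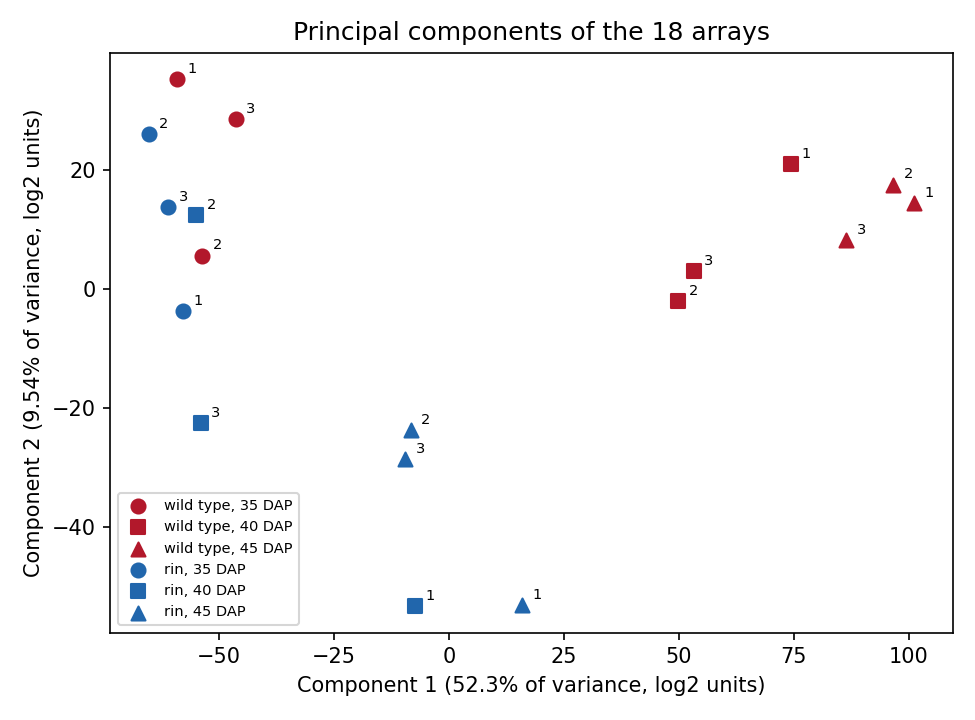
Scores of the 18 arrays on the first 2 principal components of the log2 signals (axes in log2 units, with the percent of variance), coloured by genotype, shaped by age and numbered by replicate. Wild-type arrays at 40 and 45 DAP lie right of 49.9 on the first component, and all rin arrays lie at or below 16.0.

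The mutated gene was examined first. RIN, the MADS-box regulator of ripening, gave a signal below the array's 30th percentile on all 9 rin arrays (5.106 to 9.273) and above it on all 9 wild-type arrays (62.5 to 6929). In wild type its mean was 152 ± 87.0 (SD, n = 3) at 35 DAP, 4354 ± 485 at 40 DAP and 5964 ± 838 at 45 DAP. The genotype labels were therefore not contradicted on any array, as far as this probe set can tell. Where its probes lie relative to the rin lesion was not determined here.

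At 35 DAP, when wild-type fruit was immature green, the genotypes differed at few probe sets. RIN was at least 9.41-fold lower in rin, at 5.92 ± 0.464 (SD, n = 3) against 152 ± 87.0 (adjusted p = 1.34e-05). CS2 was at least 9.78-fold higher, at 149 ± 20.2 against 13.6 ± 0.933 (adjusted p = 0.00027). These were the only 2 named genes among 26 probe sets called, 11 higher and 15 lower, while 650 had an unadjusted p under 0.05 (385.8 expected by chance). Of 5 ripening regulators, only RIN was lower. The camera result of that list (adjusted p = 0.00154, and adjusted p = 0.135 with an estimated correlation) rested on RIN, since without it adjusted p = 0.256. Adjusted over the list alone, RIN remained the only call there, 2 of 20 cell wall genes, 2 of 10 defence genes, 1 of 12 sugar and starch genes and 1 of 2 polyamine genes were lower, and 1 of 15 ethylene perception genes was higher. On the rin arrays of this age the mean log2 ratio of 3' to 5' control signals was 0.29, 1.78 and 0.89, against 0.38 to 0.68 in wild type. The count fell to 16 with the 50th percentile filter and to 7 with only the 6 arrays compared, where RIN reached adjusted p = 0.0618. It rose to 40 without replicate 1 of wild type and to 226 without replicate 1 of rin, where most were higher (132 against 94).

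At 40 DAP, the breaker stage of wild type, histidine decarboxylase (hdc) averaged 15.0 ± 16.0 (SD, n = 3) in rin and 7562 ± 802 in wild type, at least 395-fold lower (adjusted p = 1.39e-05). RIN was at least 299-fold lower and the ACC synthase gene ACS2, of ripening ethylene synthesis, at least 102-fold lower, at 6.67 ± 2.53 against 2421 ± 2862. The small heat shock gene vis1 was at least 199-fold lower, chalcone synthase CHS1 at least 134-fold lower, the osmotin-like NP24-I at least 143-fold lower, and ER1 at least 51.4-fold lower. For hdc, vis1 and CHS1 2 of the 3 rin arrays were dim, and for NP24-I 1. Higher in rin were arginase ARG2 (32.4-fold, 877 ± 638 against 19.2 ± 0.657), alpha-galactosidase AGAL (at least 25.6-fold, 2 wild-type arrays dim), expansin EXP5 (22.4-fold), TGAS118 (13.7-fold) and CS2 (at least 12.5-fold, 1 wild-type array dim). GP1, the beta subunit of polygalacturonase, was 12.1-fold higher at 12700 ± 1483 against 1119 ± 475, and the vacuolar antiporter NHX1 at least 6.19-fold higher. Without replicate 1 of rin the folds were 63.7 for ARG2, 61.7 for AGAL, 9.80 for NHX1, 71.7 for CHS1 and 320 for NP24-I. Without its replicate 2 they were 14.8 for AGAL and 452 for CHS1, and without its replicate 3 73.9 for CHS1 and 88.9 for NP24-I. Without replicate 1 of wild type they were 52.9 for AGAL, 11.9 for EXP5, 7.15 for TGAS118, 311 for vis1 and 51.8 for ACS2. Without its replicate 2 they were 28.6 for TGAS118 and 161 for ACS2, and without its replicate 3 33.8 for EXP5.

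Of 20 cell wall genes 6 were lower and 2 higher at 40 DAP (6 and 4 adjusted over the list alone). Polygalacturonase PG2 and mannanase Man4 were at least 108-fold and 91.6-fold lower, each with 1 dim rin array, and beta-galactosidase TBG4 had a log2 difference of -5.06. The endoglucanase Cel2 was at least 54.1-fold lower, with 2 dim rin arrays, while EXP5 was higher (4.49). Of 8 ethylene synthesis genes 3 were lower, among them ACS4 (33.1-fold), and 2 were higher, among them the S-adenosylmethionine synthetase SAM1 (3.56-fold, 7837 ± 2154 against 2153 ± 279). Adjusted over the list alone these counts were 4 and 2. Of 15 ethylene perception genes 4 were lower and 2 higher, with the same counts adjusted over the list alone. The receptor ETR3 (listed as LOC544279) was 10.3-fold lower, ETR4 3.5-fold lower and EIL1 1.76-fold higher. Of 13 carotenoid genes 5 were lower and none higher (5 adjusted over the list alone), including Psy1, the fruit phytoene synthase, with a log2 difference of -2.86. Without replicate 1 of rin the folds were 249 for PG2, 395 for Man4, 68.9 for ACS4, 15.7 for ETR3 and 5.58 for ETR4. Without its replicate 2 they were 57.8 for Man4 and 2.21 for ETR4, and without its replicate 3 31.7 for PG2, 33.7 for Man4 and 22.0 for ACS4. Without replicates 1 and 3 of wild type Cel2 had 33.5 and 104, and without its replicate 2 ACS4 had 51.9.

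Defence genes shifted down as a list in camera (5 of 10 lower, 6 adjusted over the list alone; adjusted p = 0.00151, and adjusted p = 0.124 with an estimated correlation), led by NP24-I and the chitinases CHI17 (at least 11.9-fold, 2 rin arrays dim) and CHI14 (at least 2.06-fold). Of 5 ripening regulators 2 were lower, 3 adjusted over the list alone. Their camera result (adjusted p = 0.00409, and adjusted p = 0.124 with an estimated correlation) was lost without RIN (adjusted p = 0.0896). In that list TDR4 was 6.68-fold lower at 837 ± 514 against 4829 ± 1064 (SD, n = 3). Aroma genes shifted down (4 of 9 lower, 5 adjusted over the list alone; adjusted p = 0.0395, and adjusted p = 0.173 with an estimated correlation). Among them lipoxygenase loxC was 38.9-fold lower, alcohol acyltransferase AAT 35.2-fold lower and hydroperoxide lyase HPL 2.78-fold lower. Without replicate 1 of rin the folds were 82.6 for loxC, 101 for AAT and 18.1 for CHI17, without its replicate 2 4.41 for TDR4, and without its replicate 3 20.3 for loxC and 14.1 for AAT. CHI17 had 6.74 and 18.1 without replicates 1 and 3 of wild type, and CHI14 0.94 and 3.93 without its replicates 1 and 2, so its bound rested on replicate 1. Sugar and starch genes divided into 1 higher and 2 lower of 12 (4 and 3 adjusted over the list alone). In the small lists, CHS1 of 2 flavonoid genes, vis1 and HSP21 of 3 heat shock genes, and ADC of 2 polyamine genes were lower, and ARF3 of 4 auxin genes was higher.

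In all, 2002 probe sets were called at 40 DAP, 1169 higher and 833 lower in rin. With only the 6 arrays compared 1075 were called, and AGAL (adjusted p = 0.0624) and TGAS118 (adjusted p = 0.0571) were no longer called. Without replicate 3 of rin the count was 61.6% of the 2002 and AAT reached adjusted p = 0.0613, ETR4 and CHI14 lost their calls under several settings (adjusted p up to 0.163 and 0.139), and the aroma list reached 0.0533 with quantile normalization, 0.0986 with no filter, 0.0666 and 0.0637 without replicates 1 and 2 of wild type, and 0.0562 without replicate 2 of rin.

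At 45 DAP, when wild-type fruit was red-ripe, the endoglucanase Cel2 was at least 305-fold lower in rin, at 3.15 ± 0.218 (SD, n = 3) against 4466 ± 1228 (adjusted p = 9.51e-08), and RIN at least 415-fold lower. Lower too were hdc (at least 207-fold), ACS2 (at least 143-fold, 41.9 ± 59.3 against 4324 ± 1414), RSI-1 (at least 146-fold), the ripening expansin EXP1 (57.6-fold, 424 ± 654 against 8026 ± 2038) and the xylosidase XYL1 (at least 9.81-fold). GP1 was 144-fold higher in rin, at 9259 ± 2746 against 77.6 ± 65.5 (adjusted p = 3.16e-08). EXP5 was at least 84.0-fold higher, the lipid transfer gene ltpg1 79.8-fold, TUB at least 64.6-fold, the chlorophyll-binding protein gene CAB6A at least 44.9-fold, TGAS118 at least 54.6-fold and LOC543809 54.9-fold. In the dimmer group 2 of 3 arrays were dim for hdc, ACS2, EXP5 and TUB, and 1 for RSI-1 and TGAS118. Without replicate 1 of rin the folds were 170 for EXP1, 502 for hdc, 278 for ACS2, 234 for RSI-1, 130 for EXP5 and 116 for CAB6A. Without its replicates 2 and 3 they were 33.2 and 33.9 for EXP1, 133 and 133 for hdc, and 28.1 and 27.7 for CAB6A. Without replicates 1, 2 and 3 of wild type ltpg1 had 34.0, 50.8 and 294, and without replicate 3 GP1 had 226 and TUB 119.

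Carotenoid genes were lower in rin at 45 DAP for 5 of 13 and higher for none (6 adjusted over the list alone), and the list passed camera (adjusted p = 0.0498, and adjusted p = 0.171 with an estimated correlation). DXS, the first enzyme of plastid isoprenoid synthesis, was 6.03-fold lower at 338 ± 65.6 against 2026 ± 263 (SD, n = 3), CrtR-b1 4.23-fold lower and the desaturase ZDS 3.59-fold lower. Of 5 ripening regulators 2 were lower (2 adjusted over the list alone). Their camera result (adjusted p = 0.0199, and adjusted p = 0.176 with an estimated correlation) was lost without RIN (adjusted p = 0.327). TDR4 was 12.9-fold lower, whereas NOR had a log2 difference of -0.51 and was not called. Ethylene synthesis divided into 3 higher and 2 lower of 8, with the same counts adjusted over the list alone. The ACC oxidase ACO6, named outside the rule, is not in that list. Its 3 probe sets were higher in rin, with log2 differences of 3.13, 4.31 and 4.87. ACS6, an ACC synthase of unripe fruit, was at least 15.2-fold higher (2 wild-type arrays dim) and SAM3 3.49-fold higher, against ACS2 and ACS4 lower. Of 15 ethylene perception genes 5 were lower and 1 higher (the same adjusted over the list alone), with ETR3 3.97-fold lower, EIL4 2.57-fold lower and EIL2 3.39-fold higher.

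Cell wall genes divided evenly at 45 DAP, with 4 of 20 higher and 4 lower (the same adjusted over the list alone). TBG4 was 8.21-fold lower, while the pectin-degrading polygalacturonase PG2 had a log2 difference of -2.37 and the mannanase Man4 one of 1.01, and neither was called. The arrays of Man4 overlapped, but those of PG2 did not, at 3695 to 5949 in rin against 20930 to 25060 in wild type. The model shares 1 spread over all groups, and PG2 scattered widely in others, from 7.426 to 914.6 in rin at 40 DAP. The missing call for PG2 therefore does not show equal levels. Of 12 sugar and starch genes 4 were higher and 3 lower (the same adjusted over the list alone). The vacuolar invertase AI was 5.05-fold lower at 3886 ± 1078 against 19150 ± 788 (SD, n = 3), hexokinase hxk1 at least 5.38-fold higher (2 wild-type arrays dim, and 8.48-fold without replicate 3 of wild type) and fructokinase FRK2 2.28-fold higher. Aroma genes gave 1 higher (LOX1.1) and 1 lower (ADH2) of 9, and defence genes 3 lower of 10, with the same counts adjusted over the list alone. Of the aroma genes not called, AAT, loxC, HPL and CCD1B were lower in rin on arrays that did not overlap, and the rest overlapped. AAT lay at 1152 to 3893 in rin against 7830 to 9873 in wild type, and loxC at 270.9 to 811 against 1627 to 3107. In the small lists, gad2 and gdh1 of 4 glutamate genes, CAB6A of 3 photosynthesis genes and TSW12 of 2 cuticle markers were higher, and CHS1 was lower. Heat shock, auxin, cell cycle and polyamine genes had no call at the probe sets that represent them. A second and dimmer probe set of the auxin gene IAA3 (mean log2 signal 3.55) was called lower in rin (log2 difference -1.67, adjusted p = 0.000963).

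The model called 2179 probe sets at 45 DAP, 1021 higher and 1158 lower. With replicates 2 and 3 of rin averaged as 1 array, 1446 were called. The majority turned there (774 higher, 672 lower), with the 2-fold threshold (860, 738), without replicates 1 and 2 of wild type (759, 742 and 827, 813) and without replicates 2 and 3 of rin (796, 679 and 766, 687). The carotenoid list lost its call with quantile normalization (adjusted p = 0.0589), no filter (0.192) both first rin arrays left out (0.0562), without replicate 2 of wild type (0.0739) and without replicate 1 of rin (0.0585), and ripening regulators lost theirs with no filter (0.0579).

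**Figure D2:**
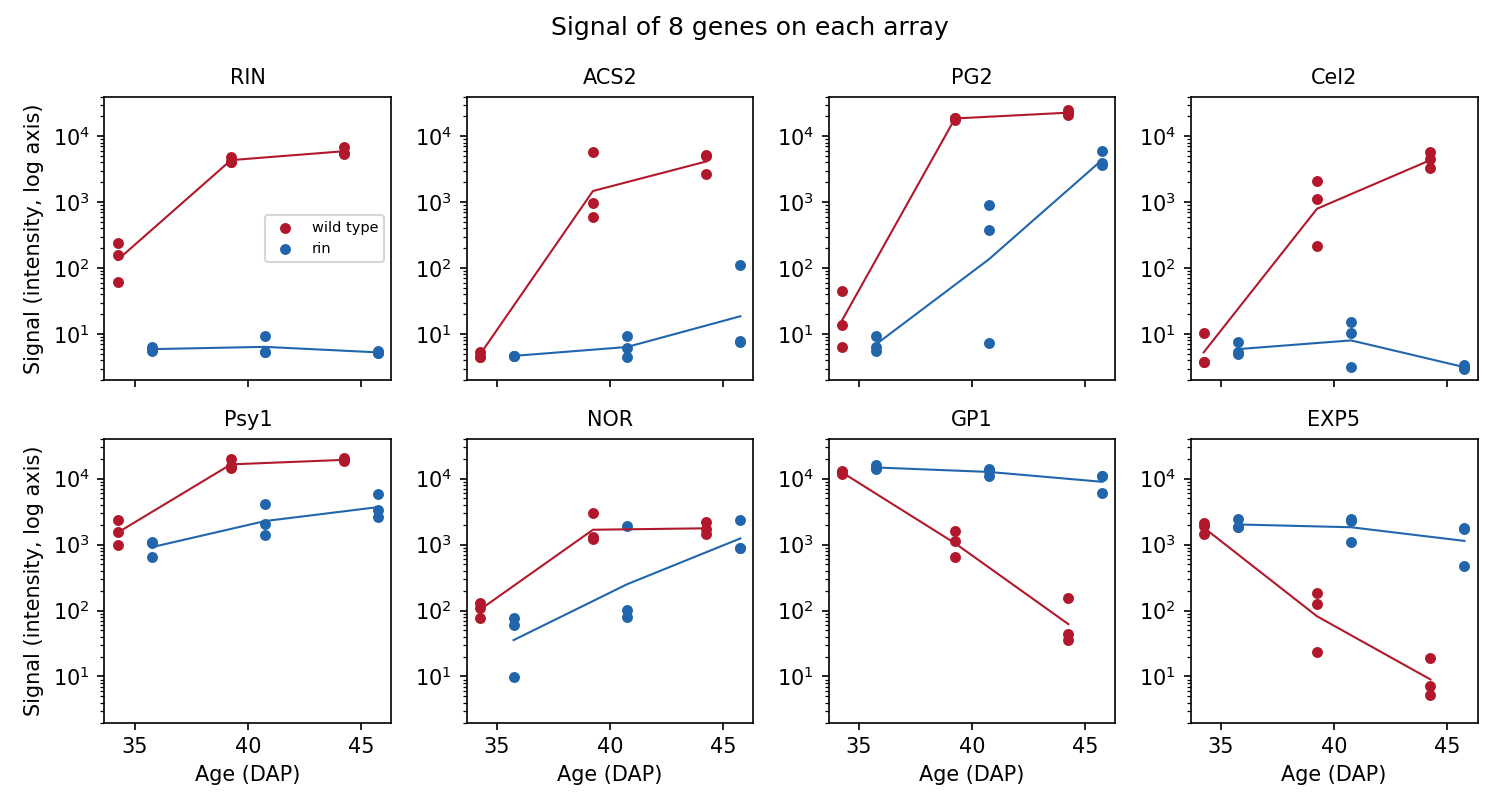
Signal of 8 genes on each array (points, intensity on a log axis) at 3 ages (DAP) in wild type and rin, with lines through the geometric mean of 3 arrays. RIN stays at or below 9.273 on every rin array and reaches 6929 in wild type, while PG2 and NOR rise with age in both genotypes.

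Between 35 and 40 DAP in wild type, the mannanase Man4 rose at least 663-fold, from 5.00 ± 0.745 (SD, n = 3) to 10030 ± 691 (adjusted p = 0.000142), hdc at least 499-fold and PG2 at least 847-fold, from 21.6 ± 20.6 with 2 dim arrays to 18590 ± 778. The glutamate decarboxylase yfe37 (GAD3) fell at least 83.5-fold and AGAL at least 49.0-fold, each with 2 dim arrays at 40 DAP, and ARG2 49.9-fold. Of 5 ripening regulators 3 rose, with log2 changes of 5.03 for RIN, 4.04 for NOR and 2.48 for TDR4, with 3 calls adjusted over the list alone. The list passed camera (adjusted p = 0.0261, and adjusted p = 0.334 with an estimated correlation), but not without RIN (adjusted p = 0.141). Of 20 cell wall genes 6 rose and 5 fell, of 13 carotenoid genes 5 rose and 1 fell, and of 9 aroma and 10 defence genes 4 and 4 rose. In that interval 2386 probe sets were called, 1116 higher and 1270 lower, but 1245 and 1236 with quantile normalization and 1237 and 1157 with median centring. The regulator list reached adjusted p = 0.0566 without replicate 1 at 40 DAP. Without replicate 1 at 35 DAP the fold of ARG2 was 78.6, without replicate 2 at 35 DAP those of ARG2 and yfe37 were 23.2 and 49.7, and without replicate 1 at 40 DAP that of AGAL was 101.

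From 40 to 45 DAP in wild type, Cel2 rose 5.47-fold (adjusted p = 0.0437), CrtR-b1 2.88-fold (0.00331) and DXS 2.83-fold (0.0118). CAB6A fell at least 45.6-fold, ltpg1 68.6-fold and glutamine synthetase GS2 at least 13.7-fold. Of 13 carotenoid genes 3 rose and none fell, while 3 of 12 sugar and starch genes fell and none rose. Fewer probe sets were called, 641, of which 275 rose and 366 fell, but 333 and 286 with log2 of the signal plus 32. The count was 298 with only the 6 arrays compared, 384 without replicate 3 at 40 DAP, and 321 and 310 without replicates 1 and 2 at 45 DAP. Cel2 lost its call under 8 settings (adjusted p up to 0.171), DXS without replicate 2 at 45 DAP and with only the arrays compared (up to 0.0797), and ltpg1 (0.0749) and CrtR-b1 (0.0527) with the latter. Without replicates 1 and 3 at 40 DAP the folds were 8.82 and 2.85 for Cel2 and 93.9 and 29.7 for CAB6A, and without replicates 2 and 3 27.6 and 8.68 for GS2. Without replicates 1, 2 and 3 at 45 DAP ltpg1 had 29.2, 43.6 and 253.

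Over the whole course from 35 to 45 DAP in wild type, PG2 rose at least 1040-fold to 22820 ± 2086 (SD, n = 3; adjusted p = 8.98e-06), hdc at least 496-fold, Cel2 at least 288-fold, ACS2 at least 274-fold, ACS4 at least 209-fold, vis1 at least 181-fold and Man4 at least 90.1-fold. Falling most were gad2 (at least 150-fold), the pectin methylesterase PMEU1 (at least 155-fold), CAB6A (at least 147-fold), AGAL (at least 119-fold), yfe37 (at least 102-fold), GP1 (202-fold, from 12570 ± 568 to 77.6 ± 65.5) and EXP5 (at least 134-fold). For PG2, ACS4 and EXP5 2 arrays of the dimmer group were dim. RIN rose 44.6-fold, NOR 17.3-fold and TDR4 10.3-fold, so 3 of 5 ripening regulators rose (3 adjusted over the list alone). Of 13 carotenoid genes 6 rose and 1 fell (the same adjusted over the list alone), with Psy1 rising 12.7-fold to 19300 ± 1168, DXS 5.76-fold and ZDS 4.99-fold. Without replicates 1 and 3 at 45 DAP the fold of Man4 was 164 and 40.1, and without replicate 3 that of GP1 was 317. Without replicates 1 and 2 at 35 DAP that of gad2 was 266 and 57.3, and without replicate 2 that of yfe37 was 60.4.

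Of 9 aroma genes in wild type, 5 rose and 1 fell over the course (6 and 1 adjusted over the list alone). AAT rose 105-fold (46.8-fold and 224-fold without replicates 2 and 3 at 35 DAP) and loxC at least 80.1-fold (1 array dim at 35 DAP), and LOX1.1 fell 16.6-fold. Cell wall genes divided into 6 up and 6 down of 20 (the same adjusted over the list alone), with TBG4 rising 24.9-fold. Sugar and starch genes divided into 4 and 4 of 12 (4 and 5 adjusted over the list alone), with FRK3 rising 2.09-fold, FRK2 falling 5.66-fold and the sucrose synthase SUS1 (listed as LOC543961) falling at least 29.1-fold (2 arrays dim at 45 DAP). Ethylene synthesis gave 2 up and 3 down of 8, with SAM1 falling 3.77-fold, and ethylene perception 5 up and 1 down of 15. Of 10 defence genes 2 rose. In the small lists 3 of 3 photosynthesis genes, 3 of 4 glutamate genes and 2 of 4 auxin genes fell, 2 of 3 heat shock genes and CHS1 rose, and cell cycle, polyamine and cuticle genes had no call. None of the 8 lists tested passed camera over this course, with the smallest adjusted p, 0.0742, for ripening regulators. A total of 3286 probe sets were called, 1825 rising and 1461 falling.

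Within rin, between 35 and 40 DAP, limma called 2 probe sets, both lower, of which the named one was the auxin-response gene IAA17, from 162 ± 60.6 to 19.8 ± 18.1 (SD, n = 3; at least 7.54-fold, 2 arrays dim at 40 DAP; adjusted p = 0.0307), while 1060 had an unadjusted p under 0.05 (385.8 expected by chance). None of the 8 lists tested passed camera. The count rested on single arrays, being 646 without replicate 1 and 1 without replicate 2 at 35 DAP, and 1, 38 and 4 without replicates 1, 2 and 3 at 40 DAP. Most were higher among the 646 (408), the 38 (26) and the 4 (3). IAA17 lost its call under 8 of 18 settings (adjusted p up to 0.699).

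Between 40 and 45 DAP in rin, 3 small heat shock genes rose and were the only named genes called. ER-SHSP rose at least 72.6-fold to 4573 ± 2855 (SD, n = 3; adjusted p = 0.0292), HSP21 at least 63.6-fold to 3328 ± 2183 (0.0358) and vis1 at least 33.0-fold to 738 ± 503 (0.0358), with 1, 1 and 2 arrays dim at 40 DAP, so 2 of 3 genes of the fixed heat shock list rose. In all 28 probe sets were called, 13 higher and 15 lower, while 897 had an unadjusted p under 0.05 (385.8 expected by chance), and no list passed camera. Most were higher with no filter (6 against 5), log2 of the signal plus 32 (14, 10), the replicate number as a block (5, 3) and raised signals (9, 7). ER-SHSP, HSP21 and vis1 lost their calls under 7, 8 and 8 of 19 settings (adjusted p up to 0.238, 0.252 and 0.252). These included the replicate number as a block (0.0525, 0.0581 and 0.0525), without replicates 2 or 3 at either age, and only the 6 arrays compared or replicates 2 and 3 at 45 DAP averaged, which both left 0 probe sets called. With no filter HSP21 and vis1 lost theirs too. Without replicate 1 at 45 DAP the folds were 118, 101 and 60.7 for ER-SHSP, HSP21 and vis1. Without replicates 1 and 3 at 40 DAP they were 168 and 38.9 for ER-SHSP, and without replicate 3 37.3 for HSP21. The count was 292, 0 and 0 without replicates 1, 2 and 3 at 40 DAP, and 51, 0 and 0 without those at 45 DAP.

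From 35 to 45 DAP in rin, PG2 rose at least 313-fold, from 7.07 ± 1.89 to 4517 ± 1245 (SD, n = 3; adjusted p = 0.00167), Man4 at least 194-fold to 3720 ± 3669, and ER-SHSP at least 112-fold. Down went yfe37 (at least 26.8-fold), XTH7 (at least 12.2-fold) and AgpL1, a starch synthesis subunit (at least 26.7-fold). For ER-SHSP, yfe37 and AgpL1 1 array of the dimmer group was dim. NOR rose at least 30.8-fold (1 array dim at 35 DAP), as 1 of 5 ripening regulators. Of 20 cell wall genes 4 rose and 2 fell (5 and 4 adjusted over the list alone), 2 of 13 carotenoid genes rose (Psy1, by 2.02, and PDS, by 1.15) and 1 fell (CrtR-b1, -1.34), and 3 of 9 aroma genes rose (4 adjusted over the list alone). Ethylene synthesis gave ACS4 up and SAM1 down of 8, ethylene perception 2 up of 15, defence 1 up of 10, and 3 of 12 sugar and starch genes fell. Of 3 heat shock genes 2 rose, and 3 of 4 auxin genes, 2 of 4 glutamate genes and 1 of 2 cell cycle genes (CYCD3) fell.

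Over that course 872 probe sets were called in rin, 463 rising and 409 falling, and no list passed camera (smallest adjusted p 0.271). Most fell instead with median centring (461 against 391), log2 of the signal plus 32 (430, 415), only the 6 arrays compared (202, 192), without replicate 1 at 45 DAP (352, 265) and without both first arrays (418, 341). Replicate 2 at 35 DAP had the highest mean log2 ratio of 3' to 5' control signals of all arrays, 1.78, and replicate 2 at 45 DAP the lowest, -0.17. The count was 1754, 267 and 386 without replicates 1, 2 and 3 at 35 DAP, 303 and 301 without replicates 2 and 3 at 45 DAP, 292 with these averaged and 394 with only the 6 arrays compared. In several of these settings yfe37 lost its call (adjusted p up to 0.146). Without replicate 1 at 45 DAP the fold was 113 for Man4 and 182 for ER-SHSP, and without replicate 1 at 35 DAP 72.0 for ER-SHSP and 51.0 for yfe37. Without replicate 2 at 35 DAP it was 18.2 for NOR, and without replicate 3 14.6 for yfe37.

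**Figure D3:**
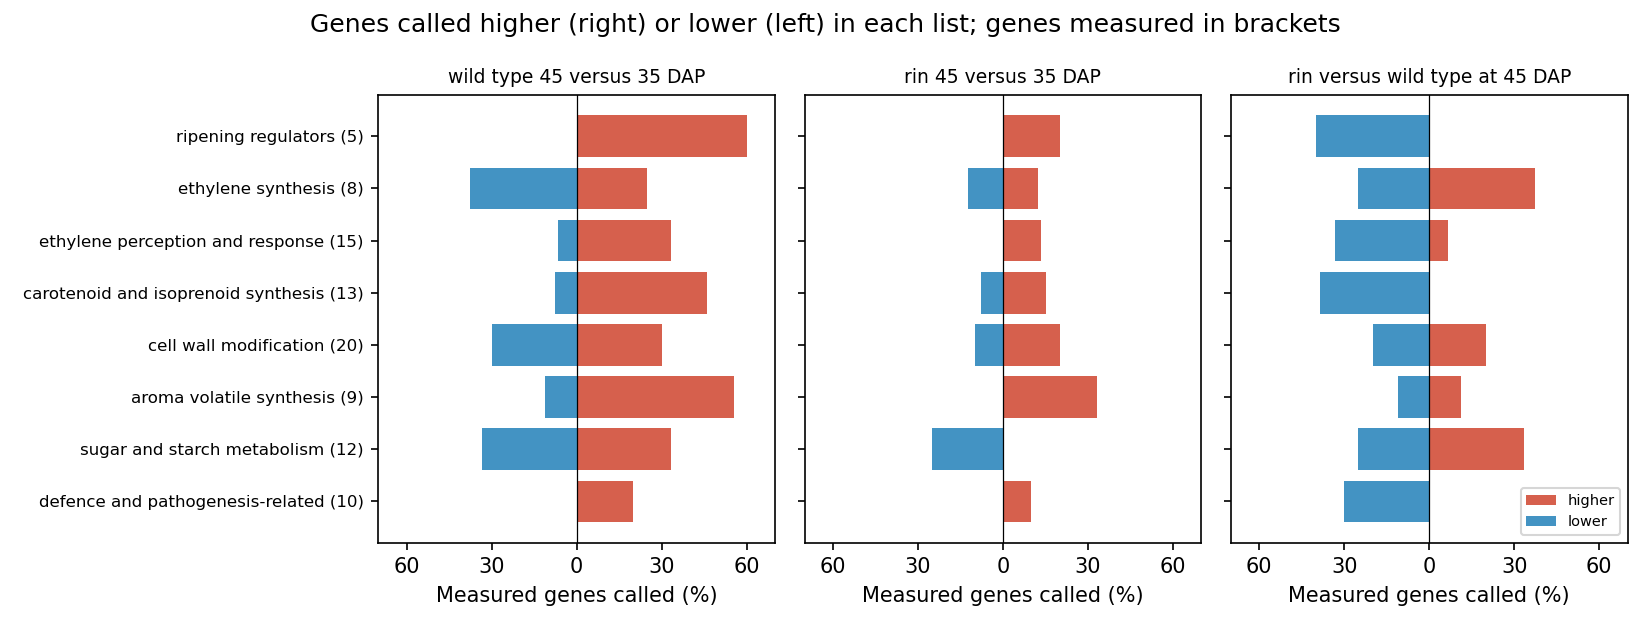
Percent of the measured genes in each of 8 lists called higher (right, red) or lower (left, blue) in 3 comparisons, with the number measured in brackets. Carotenoid genes rise in wild type (6 of 13) more than they fall (1), and 5 of 13 are lower in rin than in wild type at 45 DAP.

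The courses of the genotypes were then set against each other, with no array in common. Both were tested in the same model, with the same estimate of spread for each probe set. The numbers expected from independent lists are therefore a rough guide only. Of 1825 probe sets that rose in wild type from 35 to 45 DAP, 335 rose in rin, against 109.5 expected from independent lists, 8 fell, and 1482 were not called. Of 1461 that fell, 231 fell in rin, against 77.43 expected, 10 rose, and 1220 were not called. The log2 changes had the same sign in 80.2% and 80.4% of these. Across the 7717 probe sets, which are not independent replicates, the changes correlated with r = 0.591 and rho = 0.534. For the 2495 called with a 2-fold change in wild type, the slope of the rin change on the wild-type change was 0.334. Of the 18 probe sets called in opposite directions, the named genes, given after their values were seen, were CrtR-b1, INT4 and the ACC oxidase ACO6. For ACO6, 2 probe sets fell in wild type (log2 changes of -2.14 and -1.67) and rose in rin (4.21 and 3.87). The third and brightest ACO6 probe set was not among the 18, with a change of -1.38 in wild type that was not called (adjusted p = 0.0616) and one of 2.11 in rin (0.0306). The 566 probe sets shared in direction became 298 with only the arrays compared and 226 with replicates 2 and 3 of rin at 45 DAP averaged. They became 871, 200 and 289 without replicates 1, 2 and 3 of rin at 35 DAP, and 338, 236 and 230 without those at 45 DAP. The 18 in opposite directions became 102, 5 and 7 without the same arrays at 35 DAP, and 29, 3 and 3 without those at 45 DAP.

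The interaction tested the difference between the courses directly. From 35 to 40 DAP it called 723 probe sets, of which 427 had a more positive change in rin. The smaller change in rin was clearest for vis1, which rose in wild type (log2 change at least 7.79) and was not called in rin (adjusted p = 0.539). The same held for hdc (at least 8.96, and 0.728 in rin) and ER1 (at least 5.62, and 0.377 in rin). AGAL, ARG2 and EXP5 fell in wild type and were not called in rin. Among lists the calls were 3 lower and 1 higher of 20 cell wall genes, 2 lower of 13 carotenoid genes and 1 lower of 5 ripening regulators, and none of the 8 lists tested passed camera. Median centring moved the share with a more positive change from 59.06% to 47.83%. The count was 417 with only the arrays compared, 461 without replicate 1 of wild type at 35 DAP, 1124 and 437 without replicates 1 and 3 of rin at 35 DAP and 410 without replicate 3 of rin at 40 DAP, and AGAL lost its call under 18 of 24 settings (adjusted p up to 0.118).

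From 35 to 45 DAP the interaction called 1018 probe sets, 557 with a more positive and 461 with a more negative change in rin. Cel2 rose in wild type (log2 change at least 8.17) and was dim in rin at both ages (interaction adjusted p = 9.11e-06), as were RIN (5.48 in wild type) and XYL1 (at least 3.21). ACS2 rose in wild type (at least 8.10) and was not called in rin (adjusted p = 0.147). GP1 (-7.66 against -0.72), EXP5, TUB, CAB6A and gad2 fell in wild type and were not called in rin. PG2 and Man4, which rose in both genotypes, were not called. Of 13 carotenoid genes 3 had a more negative change in rin (5 adjusted over the list alone), namely DXS, CrtR-b1 and ZDS. Of 20 cell wall genes 2 were more negative and 2 more positive (3 and 2 adjusted over the list alone), and none of the 8 lists tested passed camera. With replicates 2 and 3 of rin at 45 DAP averaged 665 were called, and 640 without replicate 3 of rin at 45 DAP. The share with a more positive change, 54.72%, became 46.40% with median centring, 47.87% with log2 of the signal plus 32 and 49.24% without replicate 1 of rin at 45 DAP. SAM3 lost its call under 14 of 25 settings (adjusted p up to 0.114), ADH2 under 12 (0.104) and ACS6 under 6 (0.0557).

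Averaged over the 3 ages, rin differed from wild type at 2597 probe sets, 1336 higher and 1261 lower. More were lower with median centring (1386 against 1222), log2 of the signal plus 32 (1278, 1242) and without replicate 1 of rin at 35 DAP (1435, 1359). Ripening regulators were lower for 3 of 5 genes (4 adjusted over the list alone; adjusted p = 0.00301, and adjusted p = 0.0854 with an estimated correlation), a camera result lost without RIN (adjusted p = 0.0615). Carotenoid genes were lower for 6 of 13 (6 adjusted over the list alone; adjusted p = 0.0277, and adjusted p = 0.0854 with an estimated correlation). Defence genes were lower for 5 of 10 (6 adjusted over the list alone; adjusted p = 0.0106, and adjusted p = 0.155 with an estimated correlation). Of 9 aroma genes 5 were lower and 1 higher, and 6 of 15 ethylene perception genes were lower and 1 higher. Of the calls, 1069 reached a 2-fold difference, and the carotenoid list lost its call with no filter (adjusted p = 0.0808) and without replicate 1 of rin at 35 DAP (0.0565).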

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

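Of the tests in this part, those of wild-type RNA, of a swap and of wild-type fruit mixed into the rin samples, and the count of probe sets departing from a uniform scaling, were chosen only after the result was seen. Differences between the genotypes in their change with age drew attention at 723 probe sets for 40 against 35 DAP and at 1018 for 45 against 35 DAP, each by a test of the interaction itself. Other splits of the arrays could not decide on chance by this count. Of 100 drawn splits, the real one included, 8 called as many for the earlier interaction (highest other 1280) and 6 for the later (highest other 1556). Each of those kept the genotypes apart at the later age, as 9 of the 100 did for each interaction. They therefore share the large genotype difference of that age and do not show what to expect without an interaction. For the average over the ages, 1 of 100 splits, the real one, called as many (2597, highest other 607). This argues against chance only if the arrays are independent across ages, which the recurring title codes leave unsettled.

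From 35 to 40 DAP the log2 of the rin change over the wild-type change was 5.29 for AGAL, 5.26 for ARG2, 4.33 for EXP5, -10.31 for vis1, -9.55 for hdc and -8.95 for ER1. With signals raised to the 30th percentile of the array, which limits the part that dim values play, the values for vis1, hdc and ER1 were -8.88, -8.53 and -6.88. From 35 to 45 DAP it was 7.07 for gad2, 7.02 for CAB6A, 6.93 for GP1, 6.82 for EXP5, 6.61 for XET2, 6.41 for TUB, 6.40 for ltpg1, 4.08 for LOX1.1, 3.72 for ACS6, 1.91 for SAM3 and 1.51 for FRK2. On the negative side it was -10.60 for Cel2, -8.53 for hdc, -7.76 for ACS2, -6.01 for ER1, -5.64 for RIN, -5.58 for RSI-1, -4.99 for XYL1, -3 for TBG4, -2.38 for DXS, -2.18 for CrtR-b1, -1.70 for ZDS and -1.58 for ADH2. In Cel2, hdc, ACS2, ER1, RIN, XYL1, gad2 and CAB6A at least 1 of the 4 groups was dim throughout, and with the raised signals their values were -8.15, -7.60, -7.06, -5.35, -5.46, -3.20, 5.85 and 6.29. In XET2, EXP5, TUB, ACS6 and RSI-1 from 35 to 45 DAP and AGAL from 35 to 40 DAP 1 or 2 arrays of a group were dim, and the values became 6.01, 6.24, 6.17, 3.33, -5.55 and 4.96.

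Replicate 1 of rin at 40 DAP stood apart from replicates 2 and 3 of its group on the first principal component. It correlated more closely with replicate 1 of rin at 45 DAP (r = 0.967) than with them (0.878 and 0.94). Replicates 2 and 3 were not a closer pair, with r = 0.921. Replicate 2 correlated more closely with replicate 1 of rin at 35 DAP (0.952) than with its own group. For replicate 1, wild-type RNA under a rin label was argued against by its RIN signal of 5.327. A swap with an array of rin at 45 DAP was argued against by the lack of a partner out of place, since each of those arrays correlated better with its own group by at least 0.0505. RNA quality was argued against by the mean log2 ratio of 3' to 5' control signals of replicate 1, 0.51, inside the range of the others. A share of 1.01 of its shift along the wild-type change was left with that ratio in the model, which decides nothing because the ratio lay near those of replicates 2 and 3 (0.32 and 0.48). A single wrong age label and a fruit further along in ripening both stay open, and no biological explanation was tested.

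Probe sets in rin changed from 35 to 45 DAP in the wild-type direction but by less. The slope was 0.334 over the 2495 called with a 2-fold change in wild type. Wild-type fruit mixed into the rin samples was argued against by RIN, whose highest signal at 45 DAP was 5.61, against 5434 to 6929 in wild type. The value set for this test, 1992, was the slope times the wild-type signal. The slope is one of log2 changes and not a share of RNA, so 1992 does not measure the mixture needed. Replicate 1 of rin at 45 DAP alone was argued against, since without it the slope kept a share of 0.841. For one uniform scaling of the wild-type course, 4.45% of 2495 probe sets departed, just under the bound of 5% set beforehand, but 111 departures at an adjusted p under 0.05 argue against it for every probe set, among them PG2 and Man4 over and Cel2 and RIN under the scaled change. The power of this test was not measured, so few departures do not show uniformity, and no biological explanation was tested.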

How the results depend on the processing

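The settings that averaged arrays, left out both first arrays, raised dim signals or took RIN out of its list were added after seeing the data. No named gene or list reversed under any setting, although the bound on the fold of CHI14 at 40 DAP fell under 1 (0.94) without replicate 1 of wild type. The majority direction of the calls turned under some setting in 10 of 12 comparisons, as given with each, and in neither rin against wild type at 40 DAP nor wild type at 45 against 35 DAP. For the interactions, the share with a more positive change in rin moved from 59.06% to 47.83% with median centring for 40 against 35 DAP. For 45 against 35 DAP it moved from 54.72% to 46.40% with median centring, 47.87% with log2 of the signal plus 32 and 49.24% without replicate 1 of rin at 45 DAP. Of 135 named-gene results, 115 kept their call under every setting run. With only the arrays of the groups compared, the counts of called probe sets were 7 (rin against wild type, 35 DAP), 1075 (40 DAP), 298 (wild type, 45 against 40 DAP), 0 and 0 (rin, 40 against 35 and 45 against 40 DAP), 394 (rin, 45 against 35 DAP) and 417 (interaction, 40 against 35 DAP), and 298 probe sets were shared by the courses. The same setting gave more, 2305, for rin against wild type at 45 DAP (2179), 3634 for wild type at 45 against 35 DAP (3286) and 1126 for the interaction at 45 against 35 DAP (1018), and fewer, 1991, for wild type at 40 against 35 DAP (2386). Averaging replicates 2 and 3 of rin at 45 DAP, which removes 1 array, gave 1446 (45 DAP), 0 (rin, 45 against 40 DAP), 292 (rin, 45 against 35 DAP), 665 (interaction, 45 against 35 DAP) and 226 shared. For rin at 40 against 35 DAP (2 called) the count was 1 with no filter, 0 with the 50th percentile filter and 0 without both first arrays. For rin at 45 against 40 DAP (28) it was 11 with no filter, 223 without both first arrays and 16 with raised signals. The 50th percentile filter gave 16 at 35 DAP, and a 2-fold threshold gave 1069 for the average. The cause of these moves was not tested. Without RIN the list of ripening regulators lost each of its 5 camera calls (adjusted p from 0.0615 to 0.327).

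Leaving out each array in turn gave 20 to 226 called for rin against wild type at 35 DAP, 1.2e+03 (61.6% of 2002) to 1997 at 40 DAP, 310 to 675 for wild type at 45 against 40 DAP, 1 to 646, 0 to 292 and 267 to 1754 for rin at 40 against 35, 45 against 40 and 45 against 35 DAP, 410 to 1124 and 640 to 1389 for the interactions, and 200 to 871 shared by the courses. The arrays behind each move are named with the comparisons. The median interaction over all probe sets was 0.08 and -0.09 as deposited.

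With the replicate number as a block the counts were 22, 1968 and 2121 for the genotypes at 35, 40 and 45 DAP, and 1 and 8 for rin at 40 against 35 and 45 against 40 DAP. ER-SHSP, HSP21 and vis1 lost their calls there in rin at 45 against 40 DAP. Whether plants were sampled at more than 1 age is not settled. In the titles, mutant8 and mutant9 are replicates 2 and 3 of rin at all 3 ages, mutant6 is replicate 1 at 35 and 40 DAP, and control7 and control10 recur in wild type under changing and constant numbers. Between rin at 40 and 45 DAP, deviations of same-numbered samples correlated with r = 0.479, 0.483 and -0.025 for numbers 1, 2 and 3. Number 1 is mutant6 at 40 DAP but mutant3 at 45 DAP, while numbers 2 and 3 keep their codes, so these values do not follow the codes. Over all ages, deviations of same-numbered samples correlated above 0.1 in 1 of 9 pairs across genotypes, 3 of 9 within rin and 3 of 9 within wild type, and samples correlated best with their own number in 4, 4 and 3 of 9. With 3 candidates for each sample, some such matches arise without any pairing. The 3 against 3 comparisons have 10 splits of the arrays, too few for a share under 0.05. The real counts and the highest of the other splits were 26 and 4 (35 DAP), 2002 and 1 (40 DAP), 2179 and 0 (45 DAP), 2386 and 5, 641 and 101, 3286 and 1 (wild type, 40 against 35, 45 against 40 and 45 against 35 DAP), and 2 and 57, 28 and 37, 872 and 31 (rin, the same ages); 4 splits reached the count of 2 and 2 reached that of 28. With signals as measured, PG2 in wild type from 35 to 45 DAP had a fitted fold of 1450, which was 921 without replicate 1 at 35 DAP and 2450 without replicate 3. Signals under the 30th percentile, near 11.3 to 15.34, limit the folds of dim genes.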

Other observations

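The lists in this part and their tests were chosen after the main results had been seen. Photosynthesis genes, counted over an extended list of 9, fell in wild type from 35 to 45 DAP for 5 and rose for 1 (adjusted p = 0.0409, and adjusted p = 0.371 with an estimated correlation), while none was called in rin. The photosystem protein gene PsbQ averaged 116 ± 68.6 (SD, n = 3) in wild type and 1852 ± 539 in rin at 45 DAP (log2 difference 4.14, adjusted p = 1.91e-05), whereas plastocyanin PETE was lower in rin (-1.61, 0.00039). The interaction passed for that list (0.0267, and adjusted p = 0.304 with an estimated correlation). In rin against wild type the list was lower at 35 DAP (adjusted p = 0.017, and 0.555 with an estimated correlation) with no member called, and at 40 DAP (0.0377, and 0.321) with 1 lower. It did not pass at 45 DAP (0.237), with 3 higher and 1 lower. From 40 to 45 DAP in wild type it fell (1.02e-05, and 0.0315), with 3 members lower. Of 8 jasmonate and oxylipin genes at 45 DAP, 3 were higher in rin and 2 lower, with OPR3 (log2 difference 3.53) and OPR1 (4.32) higher and TomloxE (-1.26) lower. That list fell in wild type from 40 to 45 DAP (adjusted p = 0.00166, and adjusted p = 0.0315 with an estimated correlation), with 3 members lower and none higher. Of 5 MADS-box genes outside the fixed list, 3 were higher in rin at 45 DAP (adjusted p = 0.0406, and adjusted p = 0.135 with an estimated correlation), namely MADS1 (558 ± 204 against 183 ± 12.2), TDR6 (729 ± 159 against 183 ± 82.3) and LOC543885. In wild type 4 of the 5 fell from 35 to 40 DAP (adjusted p = 0.0412, and adjusted p = 0.207 with an estimated correlation) and 4 over the course (0.0191, and adjusted p = 0.13 with an estimated correlation). The interaction over the course passed too (0.0267, and adjusted p = 0.129 with an estimated correlation), with 1 member more positive in rin.

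Of 9 heat shock genes, 5 were lower in rin at 40 DAP (adjusted p = 0.00114, and adjusted p = 0.321 with an estimated correlation), and at 45 DAP none was called (median log2 difference 0.42, adjusted p = 0.394). In wild type 7 rose and 1 fell from 35 to 40 DAP (adjusted p = 0.0221, and adjusted p = 0.339 with an estimated correlation). From 40 to 45 DAP the list passed in the other direction with no member called (0.0493, and adjusted p = 0.482 with an estimated correlation). The interaction from 35 to 40 DAP passed with 3 members more negative in rin (0.00189, and adjusted p = 0.376 with an estimated correlation). In that list, 5 rose in rin from 35 to 45 DAP (adjusted p = 0.00411, and adjusted p = 0.45 with an estimated correlation) and 3 from 40 to 45 DAP (5.04e-09, and adjusted p = 0.0698 with an estimated correlation). Of 13 further expansin and xyloglucan genes, 5 fell and XYL1 rose in wild type over the course (adjusted p = 0.0191, and adjusted p = 0.244 with an estimated correlation), and 4 fell in rin (0.0107, and adjusted p = 0.45 with an estimated correlation). That list also passed downward in wild type from 40 to 45 DAP with 2 lower (0.0493, and adjusted p = 0.38 with an estimated correlation) and in rin from 35 to 40 DAP with none called (0.0457, and adjusted p = 0.625 with an estimated correlation). Of 17 antioxidant genes at 45 DAP, 3 were higher and 4 lower in rin, among them GSH1 of glutathione synthesis at 1837 ± 720 against 5525 ± 564 (adjusted p = 0.00501). Of 8 genes for 14-3-3 proteins, 3 were higher and 2 lower at 45 DAP. Of 13 ERF-type genes 1 was higher and 1 lower, of 7 metal-binding and stress genes 1 was higher, and of 11 translation genes 1 was lower. The gibberellin gene 20ox-3 was not called there, but was lower in rin at 40 DAP (log2 difference -3.54, adjusted p = 0.0102) and on average (-2.88, 0.00078), and rose in rin from 35 to 45 DAP (3.62, 0.0229). At 35 DAP its log2 difference was -4.35. It was not called there over all probe sets, only over its list alone, of which 1 gene was measured. The ERF list passed camera for rin from 40 to 45 DAP with no member called (adjusted p = 0.0205, and adjusted p = 0.326 with an estimated correlation).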
